A study of Homo sapiens with 22 samples.

How the data were processed

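RNA from 22 archival skin biopsies, fixed in formalin and embedded in paraffin, was sequenced after exome capture: 17 biopsies of necrobiosis lipoidica (NL) and 5 of control skin. Groups were taken from the sample labels, and 2 columns of the table that no label maps to a sample were not used here. Per the file headers, the authors give for each gene and sample a read count (counts) and a count scaled to gene length and library total (rpkm), beside a gene length. The submitters' processing notes name bcl2fastq 2.19.0, STAR 2.6.1c, Subread, featureCounts and the genome build hg38, without roles, settings or a strand setting. The deposited counts are whole numbers, and each deposited rpkm value equals the count divided by the column total and by the gene length plus 1 (100% of values, tolerance 1e-06). Coordinates are those of the table, on hg38. Of its rows on primary chromosomes, 93.9% carry an identifier of GENCODE release 29, and 93.6% of those have the same coordinates.

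The table holds 64253 rows. The 3974 rows on alternate haplotypes, which hold 0 counts, and 617 rows of Y-linked genes, XIST and TSIX were left out, and 59662 were kept. Total counts per library ran from 44042130 to 174606287. Reads carried no molecular identifiers that the table shows, so the counts are not counts of independent molecules.

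NL was compared with control by edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, the quasi-likelihood test with robust=TRUE, and Benjamini-Hochberg adjustment over the 22017 genes tested, with a threshold of 0.05 on the adjusted p. The common dispersion was 0.73. A change is the fitted log2 fold change of NL against control with its standard error (SE), and levels are CPM, counts scaled by edgeR to the effective total of each library, as mean ± SD over 5 control and 17 NL samples. Counts of genes changed more than 2-fold have a fitted log2 change above 1 or below -1. Of the tested genes 161 had 0 counts in every control, so their fitted folds depend on the prior count. No fold is given for them, and list medians are also given with them at a bound of 3 counts in each control library (a mean of 0.0388 CPM). Tests were two-sided.

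The 49 gene lists, with 662 symbols, the tests, the groups and the rule for named genes were fixed before the data were examined. Of the list symbols, 7 were matched by an older name. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, Benjamini-Hochberg over the 49 lists, and again with a correlation estimated for each list, with fry and on ranks. A list score is the mean log2 CPM of its tested members with a prior count of 2. The rule names the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and at least 15 of 17 NL samples on the same side of the control mean. It also names up to 4 members of each list with the smallest p, the JAK and STAT genes, and IFNG. The text gives values for some of the genes it names. Receptor segments, variable HLA genes and genes known to be absent from some genomes were left out of the largest changes. Genes named outside the rule are said to be chosen after their values were seen.

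Correlations of list scores across the 17 NL samples used 100000 permutations (exact for n = 7), with Benjamini-Hochberg over 4 relations. The smallest p these permutations can give is 1e-05.

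Library sets were found from the first principal component of log2 CPM, scaled by total counts, of 14028 protein-coding genes, after subtraction of each group's mean. Whether a change differed between the sets was tested with an interaction of set and group in edgeR. Alternatives chosen after seeing the data are the library set as a term, each set alone, immunoglobulin and T cell receptor genes left out, and the mean level of the 13 mitochondrially encoded protein-coding genes as a covariate. The mean score of T cell and macrophage markers was also used as a covariate for the interferon gamma response and the JAK and STAT genes. Mitochondrial coding genes were compared with mitochondrial ribosomal RNA genes by the difference of their mean log2 CPM in each sample (exact permutation of the samples). Alternatives chosen beforehand were other scaling methods, filters, tools (DESeq2 1.42.0, limma-voom, limma on rpkm), a covariate for the total count, a threshold on the fold, other list tests and scores, and leaving out each library in turn.

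The test was tried on simulated data of the same size, in which 22 of 100 genes with a 2-fold change and 74 of 100 with a 4-fold change were recovered, 2 unchanged genes of 21356 tested were called, and 0 of 12 unchanged lists. Those lists were random genes simulated independently of one another. The changed genes were drawn from those with a mean log2 CPM of at least 1. In the real libraries, other splits into 17 and 5 shifted a median of 13 and up to 32 of the 49 lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.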

Results

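Gene expression was measured by RNA sequencing in archival skin biopsies that had been fixed in formalin and embedded in paraffin. Necrobiosis lipoidica (NL) is a chronic inflammatory skin disease in which granulomas, compact collections of macrophages, surround altered dermal collagen. The series holds 17 NL samples and 5 control skin samples, each with its own sample number. The titles and group labels name no patient, so whether any 2 samples share a patient is not known. Every test treated the samples as independent. Libraries were made by capturing exonic sequences with probes, a method used where RNA is fragmented. The total count per library ran from 44042130 to 174606287, with a mean of 85786391 ± 23755874 in control (SD, n = 5) and 85723779 ± 35873043 in NL (SD, n = 17). Protein-coding genes took 91.0% ± 1.11 of counts in control and 85.8% ± 5.13 in NL, while immunoglobulin genes took 0.035% ± 0.036 and 4.79% ± 4.80. Pearson correlations of log2(CPM + 1), here counts scaled to the total of each library, between samples lay between 0.915 and 0.975 in control and between 0.874 and 0.987 in NL.

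With the difference between the groups removed, the libraries still fell into 2 sets that no label names and that cross the groups. Set 1 held 2 control and 7 NL libraries, and set 2 held 3 control and 10 NL libraries. The sets followed the sample numbers in the titles: except for NL replicate 6, every library of set 2 had a higher number than those of set 1. The titles do not say what the numbers stand for. The first principal component of the group-centred values took 25.8% of their variance, and the gap between the sets on it was 29.6 against 15.9 for the next widest inner gap. Gaps that set only the outermost libraries apart were not searched. Small nucleolar RNA genes took 2.77% ± 0.02 of counts in the control libraries of set 1 and 1.38% ± 0.12 in those of set 2, and 1.77% ± 0.45 against 1.06% ± 0.46 in NL. TMEM107, named after its values were seen, was higher in set 1 by 5.14 log2 units among controls and by 4.07 among NL samples. The median change of each gene list is therefore given over all samples and, after it, in set 1 and in set 2 separately.

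NL was first compared with control skin gene by gene, to ask which transcripts differ in lesions. Of 22017 genes tested with edgeR, 4045 differed at an adjusted p below 0.05, with 2237 higher and 1808 lower in NL. More than 2-fold changes were met by 2914 of them, 1727 higher and 1187 lower. With set 2 alone, an alternative chosen after seeing the data, 2419 genes passed, 1387 higher and 1032 lower, and 1800 of these calls exceeded 2-fold. A test against a change of 2-fold itself, in place of a test against 0, passed 847 genes, 637 higher and 210 lower.

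The 10 largest rises under the naming rule are given first. SPP1 (osteopontin, a secreted phosphoprotein made by activated macrophages, chromosome 4, 87975650 to 87983426) was at 15.4 ± 13 CPM in control and 1521 ± 1631 CPM in NL (SD, n = 5 and 17), a log2 change of 6.63 ± 1.14 (SE, adjusted p = 0.000322). IL4I1, an L-amino acid oxidase of antigen-presenting cells (chromosome 19, 49889654 to 49929539), rose from 0.535 ± 0.379 to 41.6 ± 15.6 CPM, by 6.27 ± 0.53 (adjusted p = 6.94e-08). PLA2G2D, a secreted phospholipase A2 of dendritic cells and macrophages (chromosome 1, 20111939 to 20119566), rose by 8.09 ± 1.15 (adjusted p = 3.28e-05). MZB1 and DERL3, which act in the endoplasmic reticulum of antibody-secreting cells, rose by 7.62 ± 1.61 and 7.30 ± 1.34. OLR1, a scavenger receptor for oxidised lipoprotein, rose by 6.18 ± 1.30, STRA6, a retinol transporter, by 6.07 ± 0.98, and IBSP, a bone sialoprotein, by 6.43 ± 1.85. IBSP missed the threshold without control replicate 5 (6.22, adjusted p = 0.052). MIR650 (10.37 ± 2.35) and IGLL5 (6.81 ± 1.78) lie within the immunoglobulin lambda locus, where their reads and those of immunoglobulin segments can overlap, so both values are uncertain. IBSP was above the control mean in 16 of 17 NL samples and each of the other 9 genes in all 17.

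The 10 largest falls under the same rule follow. DCD (dermcidin, an antimicrobial peptide of eccrine sweat, chromosome 12, 54644591 to 54648493) was at 1210 ± 1143 CPM in control and 11 ± 23.8 CPM in NL, a log2 change of -6.77 ± 1.51 (adjusted p = 0.00319). PIP, a secretory protein of apocrine and other exocrine glands (chromosome 7, 143132077 to 143139746), fell from 46.8 ± 54.7 to 0.231 ± 0.425 CPM, with a change of -7.59 ± 1.11 (adjusted p = 7.02e-05). MUC7, a secreted mucin, changed by -7.41 ± 1.11, and SCGB1D2, a secretoglobin, by -6.36 ± 1.28. Hair keratins and hair-associated genes had very uneven control levels. KRT25, of the inner root sheath (chromosome 17, 40748021 to 40755332), was at 71.3 ± 101 CPM in control and 0.104 ± 0.267 in NL, a change of -9.64 ± 1.22 (adjusted p = 1.47e-05). KRT85 changed by -9.43 ± 1.46, KRTAP16-1 by -8.72 ± 1.38 (-4.96 without control replicate 5), PRR9 by -7.93 ± 1.33 and KRT83 by -6.31 ± 1.57. The change of KRTAP3-3 (-8.62 ± 1.70, adjusted p = 0.00122) rested on control replicate 5, without which it was 0.19 (adjusted p = 0.971). Hair keratins are close paralogs, and reads shared between them were not separable here.

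The title of the series names Janus kinases (JAKs), the tyrosine kinases that carry cytokine receptor signals to STAT transcription factors, so the genes of this pathway were compared next. Of the 11 JAK and STAT genes, 7 rose in NL, none fell and 4 did not pass (8 rose adjusted over the list alone). JAK3, which pairs with the common gamma chain of lymphocyte cytokine receptors (chromosome 19, 17824780 to 17848071), rose most, from 12.1 ± 8.73 to 85.2 ± 23.7 CPM, by 2.82 ± 0.32 log2 units (adjusted p = 2.09e-06). TYK2 rose by 1.24 ± 0.15 (adjusted p = 2.99e-06), STAT5A by 1.15 ± 0.20 and STAT2 by 0.96 ± 0.16. JAK2 rose by 0.80 ± 0.25 (adjusted p = 0.025), a call that ended without control replicates 2, 3 or 5 in turn (0.79, 0.65 and 0.79, adjusted p up to 0.112). JAK1 (-0.27 ± 0.14, adjusted p = 0.203) and STAT3 (0.53 ± 0.21, 0.0853) were among those that did not pass, though STAT3 passed without control replicate 4 (0.75). The median over the list was 0.80, with 1.07 in set 1 and 0.63 in set 2, and the list was higher as a set (camera adjusted p = 4.06e-06, and 0.0107 with an estimated correlation). The T cell and macrophage lists, given below, had higher scores than the control mean in the same 17 NL samples. With their mean score as a covariate, a test chosen after seeing the data, the JAK and STAT median was 0.44, and JAK3 (1.46, adjusted p = 0.0281) and TYK2 (1.13, adjusted p = 0.0249) passed while STAT5A (0.33), STAT2 (0.68) and JAK2 (0.54) did not. That score had r = 0.88 with the group, so the 2 were only partly separable.

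**Figure D1:**
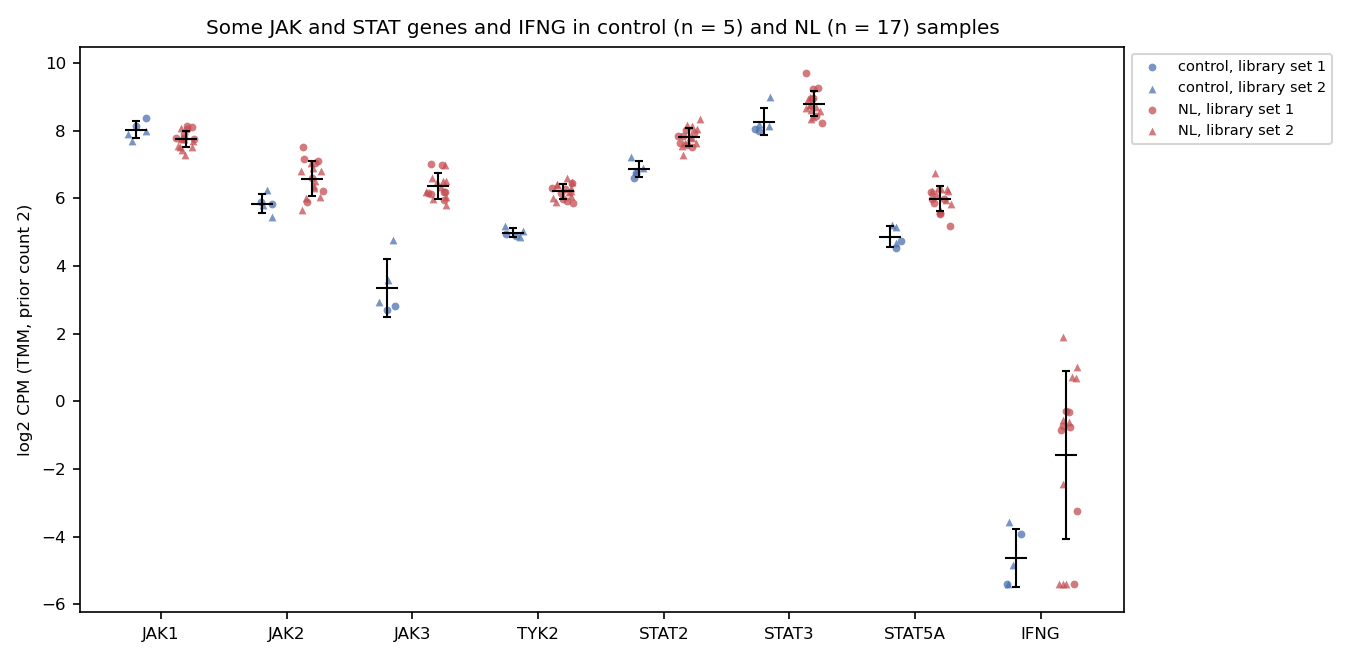
Each point is the log2 CPM of 1 gene in 1 sample, blue for control (n = 5) and red for NL (n = 17), circles for library set 1 and triangles for library set 2, with black lines for the mean and SD of each group. JAK3, TYK2 and STAT2 stand higher in NL, while JAK1 overlaps between the groups.

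Receptors that act through JAKs and the feedback inhibitors of the pathway were compared as well. Of the 23 receptor genes, 14 rose, 2 fell and 7 did not pass (15 and 2 adjusted over the list alone). IL12RB1, of the interleukin 12 and 23 receptors, rose by 2.99 ± 0.37, IL2RG, the common gamma chain, by 2.93 ± 0.37, IL10RA by 2.45 ± 0.28 and CSF2RB by 2.25 ± 0.26. LIFR (-1.45 ± 0.35) and IL6ST (-0.82 ± 0.20), chosen after their values were seen, were the 2 that fell. The list had a median of 0.98 (1.60 and 0.87) and was higher as a set (adjusted p = 1.22e-09), a call lost with an estimated correlation (adjusted p = 0.0617). Among the 16 JAK-STAT feedback genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). PTPN6, a phosphatase of blood cells, rose by 2.21 ± 0.27, CISH by 2.12 ± 0.43 and SOCS3 by 2.92 ± 0.76 (4.74 without control replicate 4, and 2.17 in set 2 alone, adjusted p = 0.194). PTPN11, named after its value was seen, changed by -0.52 ± 0.17, and its call ended without each of 8 libraries in turn (3 control and 5 NL, -0.54 to -0.43, adjusted p up to 0.148). The feedback list as a whole did not pass (median -0.10, 0.06 and 0.01, mean 0.52, adjusted p = 0.245).

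Cytokine transcripts that signal through JAKs were scarce. Of the 23 genes 16 were measurable, 4 rose, none fell and 12 did not pass (7 rose and 1 fell adjusted over the list alone). IFNG, encoding interferon gamma (chromosome 12, 68154768 to 68159747), was at 0.0229 ± 0.0275 CPM in control and 0.805 ± 0.962 CPM in NL, and was above the control mean in 13 of 17 NL samples (log2 change 5.03 ± 1.65, adjusted p = 0.0343). That call ended without each of the 5 control samples in turn (4.70 to 5.78, adjusted p up to 0.0829). IL27 stood at 0.00179 ± 0.00400 CPM in control and 0.216 ± 0.180 in NL, and OSM at 0.00758 ± 0.0118 and 0.185 ± 0.170. IL23A stood at 0.00536 ± 0.0120 CPM in control and 0.145 ± 0.136 in NL. The changes of OSM and IL23A were 4.26 and 4.29, and their calls ended without control replicates 2, 3, 4 or 5 in turn, with changes of similar size (3.98 to 4.38 and 4.03 to 4.09, adjusted p up to 0.0719 and 0.102). The call of IL23A also ended without NL replicates 4 or 5 (4.21 and 4.09, adjusted p = 0.0511 each). Its call held without control replicate 1, the only control with counts of IL23A. That fold depends on the prior count and is not given. The list median of 1.42 (3.88 and 0.24) became 2.18 without control replicate 3 and 3.14 without control replicate 4. The list was higher as a set (adjusted p = 0.00611), but not with an estimated correlation (adjusted p = 0.163) nor in set 2 alone (adjusted p = 0.18).

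Lists of genes induced by interferons and of MHC class II presentation were higher in NL. Of 22 interferon gamma response genes, 19 rose, none fell and 3 did not pass (20 rose adjusted over the list alone), with a median of 1.79 (2.55 and 1.51) and a higher score than the control mean in all 17 NL samples. CD274, encoding the checkpoint ligand PD-L1, rose by 3.98 ± 0.62, IRF1 by 2.41 ± 0.39, GBP1 by 2.27 ± 0.35 and GBP2 by 1.55 ± 0.24, the last pair being guanylate-binding proteins with close paralogs. The list passed with the preset correlation (adjusted p = 5.65e-15) and with an estimated correlation (adjusted p = 0.0391). Of 22 type I interferon response genes, 11 rose and none fell (12 adjusted over the list alone). OAS1 rose by 1.51 ± 0.28, XAF1 by 1.48 ± 0.20, IFIH1 by 1.05 ± 0.23 and IFI27 by 2.10 ± 0.49. Their median was 0.89 (1.26 and 0.59, adjusted p = 1.23e-05), a call lost with an estimated correlation (adjusted p = 0.0626). Of 12 MHC class II presentation genes, 11 rose and none fell, with the same numbers adjusted over the list alone, and LGMN (-0.18), named after its value was seen, did not pass. HLA-DPB1 rose by 2.61 ± 0.28, IFI30 by 2.83 ± 0.36 and CD74, the invariant chain, by 2.22 ± 0.33, from 443 ± 116 to 2066 ± 872 CPM. The list median was 2.26 (2.33 and 2.25, adjusted p = 4.62e-12, and 0.0391 with an estimated correlation).

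The granuloma macrophage, general macrophage and lysosome lists were higher in NL with the preset correlation. Of 18 granuloma macrophage genes, 14 rose and none fell (17 adjusted over the list alone), with a median of 3.44 (4.95 and 3.25), or 3.33 with the gene that had no control counts at its bound. TREM2, a lipid-sensing receptor, rose by 5.88 ± 0.79, ADAMDEC1 by 4.94 ± 0.67, SLAMF8 by 4.13 ± 0.48 and LYZ, lysozyme, by 3.98 ± 0.48, from 73.5 ± 43.3 to 1162 ± 559 CPM. This list passed with the preset and the estimated correlation (adjusted p = 3.16e-15 and 0.019). Of 18 general macrophage markers, 12 rose and none fell (17 adjusted over the list alone), with a median of 1.72 (2.74 and 1.45, adjusted p = 1.85e-12), lost with an estimated correlation (adjusted p = 0.0617). MARCO, a scavenger receptor, rose by 4.21 ± 0.71, C1QA, a complement subunit, by 2.59 ± 0.33, FCER1G by 2.27 ± 0.35 and CSF1R by 1.68 ± 0.26. Of 20 lysosome genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone). The proteases CTSB (2.22 ± 0.24), CTSZ (1.58 ± 0.34) and CTSD (1.05 ± 0.21) rose, and LAMP1 (-0.71 ± 0.17), named after its value was seen, fell. The lysosome median was 0.60 (1.04 and 0.17, adjusted p = 0.001), lost with an estimated correlation (adjusted p = 0.296) and in set 2 alone (adjusted p = 0.0569).

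Of 16 macrophage lipid handling genes, 5 rose and none fell (5 and 2 adjusted over the list alone). Besides OLR1, these were ABCA1, a cholesterol exporter (1.36 ± 0.24), NR1H3, the liver X receptor alpha (1.76 ± 0.45), NPC1 (0.74 ± 0.19) and NPC2 (0.88 ± 0.26), the last named after its value was seen. NPC2 missed the threshold without control replicates 1 or 2 (0.81 and 0.76, adjusted p up to 0.0667). The list did not pass as a set (median 0.72, 0.83 and 0.52, adjusted p = 0.0512), but lay at the threshold: leaving out 1 of 10 libraries took it past (median 0.61 to 0.78).

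The T cell, Th1 and T cell regulation lists were higher in NL with either correlation. Of 17 T cell markers, 16 rose and none fell (17 adjusted over the list alone), with a median of 2.38 (3.72 and 2.0), and the list passed with the preset and the estimated correlation (adjusted p = 4.12e-17 and 0.035). CD3E rose by 2.79 ± 0.37, CD6 by 2.24 ± 0.33 and CD4 by 1.83 ± 0.28. Of 10 Th1 genes, 5 rose and none fell (6 adjusted over the list alone), with a median of 1.67 (3.14 and 1.58, adjusted p = 5.6e-06, and 0.0272 with an estimated correlation). HAVCR2 rose by 2.6 ± 0.35 and CXCR3 by 4.59 ± 1.06 (8.33 without control replicate 5). Of 10 T cell regulation genes, 7 rose and none fell (8 adjusted over the list alone), with a median of 1.98 (3.36 and 1.79, adjusted p = 1.99e-06, and 0.0107 with an estimated correlation). IL2RA rose by 3.25 ± 0.68, LAG3 by 2.02 ± 0.53 and FOXP3, the regulatory T cell factor, by 2.02 ± 0.54. Cytotoxic genes rose in 5 of 12 (8 adjusted over the list alone), none fell, and their median was 1.60 (3.60 and 1.25, adjusted p = 1.38e-05), lost with an estimated correlation (adjusted p = 0.0896). NKG7 rose by 2.77 ± 0.66 and GNLY, granulysin, by 1.85 ± 0.50. GZMH (2.37 ± 0.83), named after its value was seen, lost its call without each of 16 libraries in turn (4 control and 12 NL, 2.05 to 2.42, adjusted p up to 0.137), and its change was 4.30 without control replicate 4.

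The Th2 and Th17 lists did not pass as sets. Of 12 Th2 genes 8 were measurable, 2 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.90, 1.67 and 1.12, 0.58 to 1.42 without 1 control in turn, adjusted p = 0.33). The Th2 score was above the control mean in 15 of 17 NL samples. The 2 genes that rose were CCR4 (2.39 ± 0.73, adjusted p = 0.0241) and CCL17 (5.48 ± 1.90, adjusted p = 0.0451). The stability of these 2 calls is not given here. The gene that fell was GATA3 (-1.63 ± 0.34), a factor of Th2 cells that keratinocytes and gland cells also express, from 335 ± 178 to 109 ± 62.5 CPM. Of 10 Th17 genes 6 were measurable, 2 rose and 1 fell (3 and 2 adjusted over the list alone, median 1.10, 2.24 and 0.91, 0.74 to 2.43 without 1 control in turn, adjusted p = 0.328). CCL20, a chemokine, had no counts in any control and 0.166 ± 0.151 CPM in NL. AHR changed by -0.81 ± 0.22, and by -0.64 without control replicate 3, which ended its call (adjusted p = 0.078). It was -0.26 in set 1 alone and -0.26 with the level of mitochondrially encoded RNA as a covariate (adjusted p = 0.398 and 0.333).

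Plasma cell and B cell lists were each higher in NL with the preset correlation. Of 9 plasma cell markers, 8 rose and none fell (9 adjusted over the list alone), with a median of 5.45 (5.71 and 5.90), or 4.47 with the gene that had no control counts at its bound. POU2AF1, a coactivator of antibody-producing cells, rose by 5.45 ± 1.23, beside MZB1 and DERL3. The list passed (adjusted p = 5.6e-06), but not with an estimated correlation (adjusted p = 0.0963). Of 12 B cell markers, 2 rose and none fell (1 adjusted over the list alone), with a median of 1.48 (3.11 and 1.11), which was 2.89 without control replicate 5. CD79A, a chain of the B cell receptor that plasma cells also carry, rose by 5.93 ± 1.59, and MS4A1, encoding CD20, had a change of 2.70 ± 1.02 (adjusted p = 0.0685), and passed without control replicate 5 (3.63) and without NL replicates 1 or 13 (2.79 each). The B cell list was higher as a set (adjusted p = 0.00825), a call lost with an estimated correlation (adjusted p = 0.325).

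The dendritic cell and neutrophil lists did not pass as sets. Of 13 dendritic and Langerhans cell markers, 2 rose and none fell, with the same numbers adjusted over the list alone, with a median of 0.59 (0.81 and 0.06, 0.16 to 0.90 without 1 library in turn, adjusted p = 0.298). CLEC10A, a lectin of dendritic cells and macrophages, rose by 2.50 ± 0.40. Of 11 neutrophil markers 9 were measurable, 3 rose and none fell (4 and 1 adjusted over the list alone), with a median of 0.97 (1.58 and 1.81, adjusted p = 0.267), turning to -0.06 and -0.07 without control replicates 3 and 4. FPR1 rose by 3.19 ± 0.78 and CSF3R by 2.0 ± 0.45, and macrophages express both. Of 9 mast cell markers, none rose and 2 fell, with the same numbers adjusted over the list alone. KIT changed by -1.52 ± 0.32, and melanocytes share this receptor. The mast cell median was -0.71 (-0.14 and -0.92), and -0.40 without control replicate 5. The list was lower (adjusted p = 0.00662), but not with an estimated correlation (adjusted p = 0.296) nor in set 1 alone (adjusted p = 0.182).

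**Figure D2:**
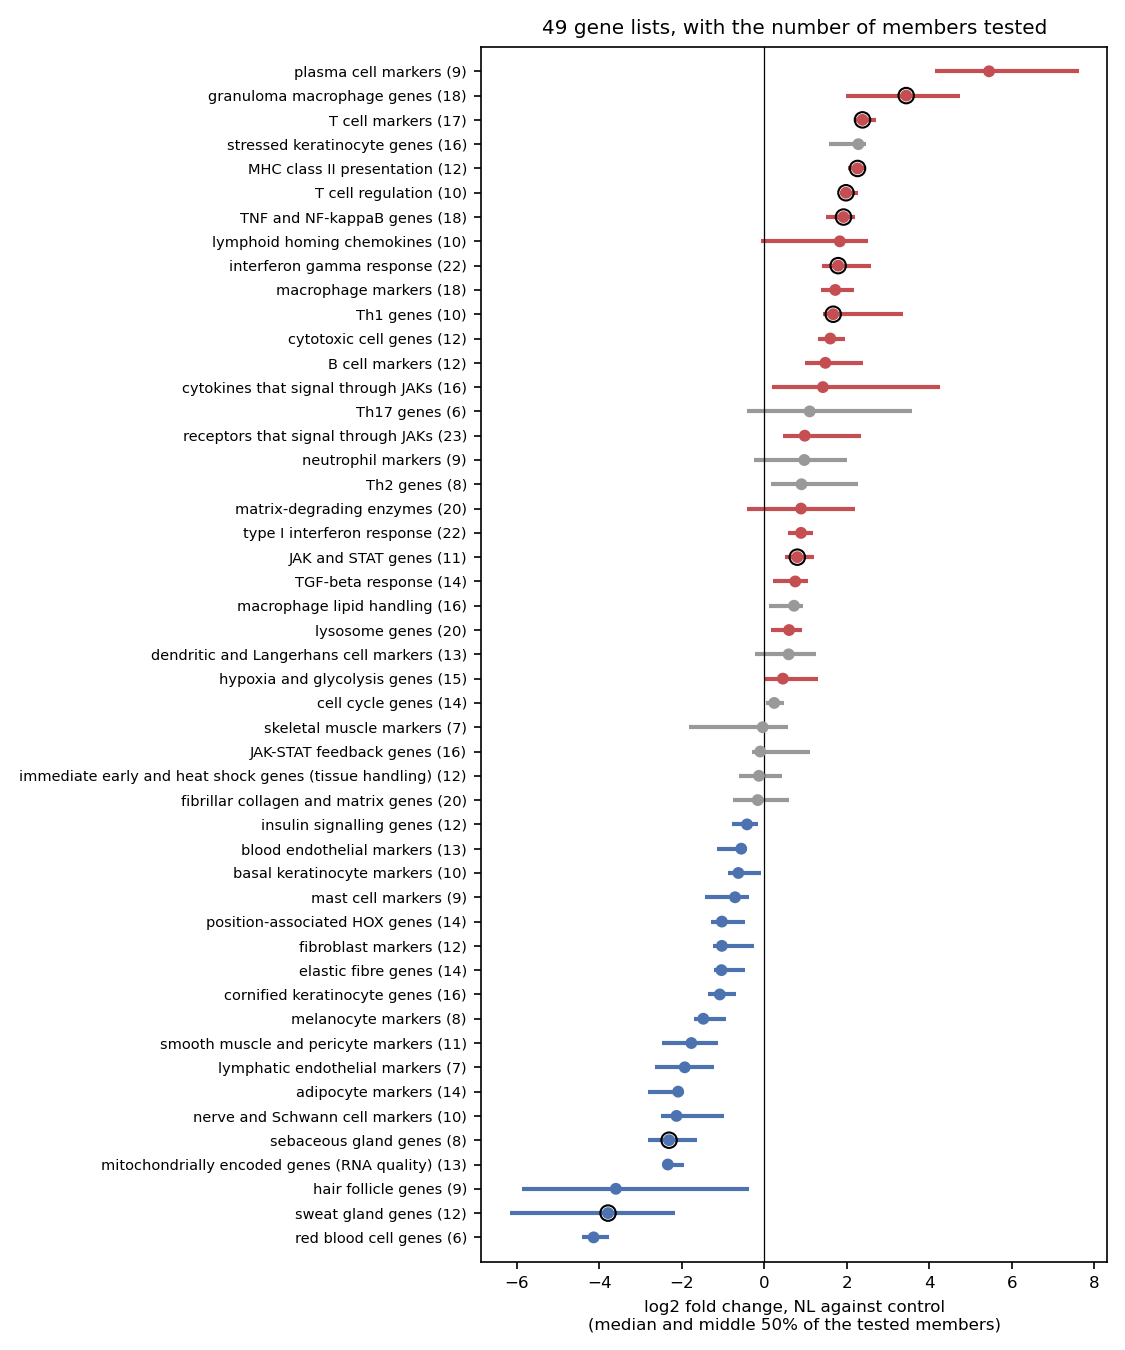
Points give the median log2 fold change, NL (n = 17) against control (n = 5), over the tested members of each of the 49 gene lists, and bars the middle 50% of members. Red and blue mark lists shifted up and down at an adjusted p below 0.05, grey the others, and black rings the 10 lists whose call held with an estimated correlation. Plasma cell markers stand highest at 5.45 and red blood cell genes lowest at -4.14.

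Inflammatory signalling was read from TNF and NF-kappaB genes and lymphoid homing chemokines. Of 18 TNF and NF-kappaB genes, 13 rose and none fell (16 adjusted over the list alone), with a median of 1.92 (2.24 and 1.81, adjusted p = 5.42e-13, and 0.0289 with an estimated correlation). CCL3, a macrophage chemokine with near-identical gene copies and therefore uncertain, rose by 5.89 ± 0.69, TRAF1 by 2.01 ± 0.28 and NFKB2 by 1.83 ± 0.23. Of 10 lymphoid homing chemokine genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone). CXCR4 rose by 2.33 ± 0.47, CCL19 by 1.84 ± 0.43 and CXCL16 by 1.68 ± 0.30, while CXCL12 changed by -0.98 ± 0.26. CXCL13 (3.95 ± 1.36), named after its value was seen, lost its call without each of 12 libraries in turn (5 control and 7 NL, 3.63 to 4.62, adjusted p up to 0.104). Its call also ended with the library set as a term (2.97, adjusted p = 0.104). This list had a median of 1.83 (2.88 and 1.49, adjusted p = 0.0168), and its call was lost with an estimated correlation (adjusted p = 0.248), on ranks (adjusted p = 0.0585) and in set 2 alone (adjusted p = 0.0974).

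Genes of the dermal matrix moved in both directions. Of 20 fibrillar collagen and matrix genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not shift (median -0.16, 0.81 and -0.54, mean 0.01, adjusted p = 0.887). In set 1 alone it was higher (adjusted p = 0.0035). FN1, fibronectin, rose from 3015 ± 1711 to 14550 ± 7690 CPM, by 2.27 ± 0.49, and COL11A1 rose by 2.22 ± 0.58. SPARC (-1.38 ± 0.35) and COL14A1 (-1.37 ± 0.38) fell, and both missed the threshold without control replicate 3 (-1.08 for each, adjusted p = 0.0545 and 0.0786). COL12A1 (0.70 ± 0.24) and LOX (-1.07 ± 0.32), the other 2 to pass, were named after their values were seen. COL12A1 missed the threshold without each of 12 libraries in turn (4 control and 8 NL, 0.57 to 0.74, adjusted p up to 0.142), and LOX without control replicates 3 or 5 (-0.84 and -0.87, adjusted p up to 0.118). Of 14 elastic fibre genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with a median of -1.04 (-0.58 and -1.09). ELN, elastin, changed by -2.49 ± 0.53, from 364 ± 259 to 65.0 ± 50.6 CPM, FBLN1 by -1.55 ± 0.36, LTBP1 by -1.17 ± 0.19, and EMILIN1 by 1.41 ± 0.24. LTBP4 (-1.03 ± 0.27) and FBLN5 (-1.48 ± 0.43), named after their values were seen, missed the threshold without control replicate 2 (LTBP4, -0.79, adjusted p = 0.0707) and without control replicates 3 or 5 (FBLN5, -1.41 and -0.94, adjusted p up to 0.187). The elastic list was lower (adjusted p = 0.00212), but not with an estimated correlation (adjusted p = 0.248) nor in set 1 alone (adjusted p = 0.102).

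Fibroblast markers, matrix-degrading enzymes and TGF-beta response genes bear on matrix turnover. Of 12 fibroblast markers, none rose and 4 fell (6 adjusted over the list alone), with a median of -1.03 (-0.12 and -1.31). CD34, carried by dermal fibroblasts and endothelium, changed by -2.50 ± 0.46, and DCN, decorin, by -1.20 ± 0.31, from 1959 ± 643 to 851 ± 426 CPM. The list was lower (adjusted p = 0.00567), but not with an estimated correlation (adjusted p = 0.316) nor in set 1 alone (adjusted p = 0.561). Of 20 matrix-degrading enzyme genes, 8 rose and none fell, with the same numbers adjusted over the list alone. MMP12, macrophage elastase, rose by 5.70 ± 1.15, PLAUR by 2.65 ± 0.45 and PLAU, urokinase, by 2.16 ± 0.36. The enzyme median was 0.89 (2.50 and 0.38), and 2.24 without control replicate 4. The list was higher (adjusted p = 0.00446), but not with an estimated correlation (adjusted p = 0.249) nor in set 2 alone (adjusted p = 0.32). Of 14 TGF-beta response genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.75 (1.12 and 0.63, adjusted p = 0.00507), lost with an estimated correlation (adjusted p = 0.234) and in set 2 alone (adjusted p = 0.0818). TGFB1 rose by 1.34 ± 0.28, while TGFB2 changed by -1.51 ± 0.36.

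The epidermis was read from cornified, basal and stressed keratinocyte genes. Of 16 cornified keratinocyte genes, none rose and 6 fell (8 adjusted over the list alone), with a median of -1.08 (-1.06 and -1.14, adjusted p = 1.45e-05), lost with an estimated correlation (adjusted p = 0.234). DSC1, a desmosomal cadherin, changed by -2.10 ± 0.29, from 1199 ± 154 to 281 ± 132 CPM, and DSG1 by -1.53 ± 0.30. Of 10 basal keratinocyte markers, none rose and 4 fell (5 adjusted over the list alone), with a median of -0.63 (-0.33 and -0.83, adjusted p = 0.00611), lost with an estimated correlation (adjusted p = 0.296) and in set 1 alone (adjusted p = 0.0577). TP63, the basal transcription factor, changed by -1.11 ± 0.33, and missed the threshold without control replicates 4 or 5 (-0.97 and -0.96, adjusted p up to 0.0832), in set 1 alone (-0.23, adjusted p = 0.815) and with the level of mitochondrially encoded RNA as a covariate (-0.91, adjusted p = 0.147). None of 16 stressed keratinocyte genes passed, with the same numbers adjusted over the list alone. KRT6A, a keratin of wounded epidermis with near-identical copies, stood at 1609 ± 2408 CPM in control and 7757 ± 10160 in NL (2.27 ± 1.30, adjusted p = 0.256), and was above the control mean in 10 of 17 NL samples. The list median was 2.28 (3.56 and 1.35, adjusted p = 0.266), and the list passed without control replicate 4 (median 3.81, adjusted p = 0.0419) and in set 1 alone (adjusted p = 0.0394).

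Lists of sweat gland, sebaceous gland and hair follicle genes were lower in NL with the preset correlation. Of 12 sweat gland genes, 11 fell and none rose, with the same numbers adjusted over the list alone, with a median of -3.79 (-4.35 and -2.62), and all 17 NL samples lay below the control mean of the list score. MUCL1 changed by -4.88 ± 0.93, from 262 ± 217 to 8.88 ± 10.9 CPM, and KRT8, a simple epithelial keratin, by -2.09 ± 0.40. This list passed with the preset and the estimated correlation (adjusted p = 1.48e-09 and 0.0391). Of 12 sebaceous gland genes 8 were measurable, 3 fell and none rose (4 adjusted over the list alone), with a median of -2.31 (-3.79 and -2.01, adjusted p = 0.00453, and 0.0434 with an estimated correlation). ELOVL3, a fatty acid elongase, changed by -3.65 ± 0.82, and missed the threshold without control replicate 1 (-2.09, adjusted p = 0.127). Of 12 hair follicle genes 9 were measurable, 4 fell and none rose, with the same numbers adjusted over the list alone. TCHH, trichohyalin, changed by -4.45 ± 0.89, beside KRT25 and KRT85. The hair median was -3.60 (-3.78 and -4.55), and -2.22 without control replicate 1. The hair list was lower (adjusted p = 0.00543), but not with an estimated correlation (adjusted p = 0.248) nor with a filter of at least 1 CPM in 5 samples (median -1.05, adjusted p = 0.102).

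**Figure D3:**
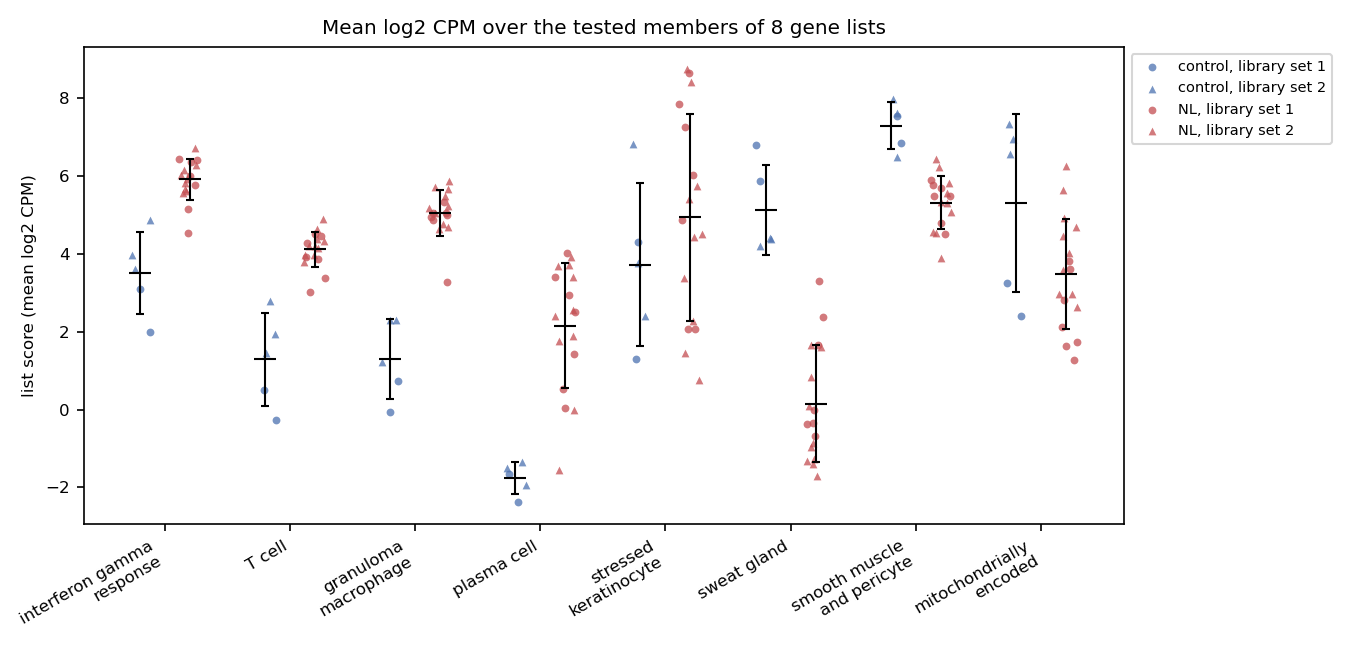
Each point is the mean log2 CPM over the tested members of 1 gene list in 1 sample, blue for control (n = 5) and red for NL (n = 17), circles for library set 1 and triangles for library set 2, with black lines for the mean and SD of each group. The sweat gland score lies below the control mean in all 17 NL samples, and the mitochondrially encoded score is lower in set 1 than in set 2 among controls.

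Smooth muscle, blood endothelial and lymphatic lists were lower in NL with the preset correlation. Of 11 smooth muscle and pericyte markers, 9 fell and none rose (11 adjusted over the list alone), with a median of -1.77 (-1.34 and -1.84, adjusted p = 3.81e-08), lost with an estimated correlation (adjusted p = 0.0617). MYH11, smooth muscle myosin, changed by -3.01 ± 0.43, from 2674 ± 1890 to 332 ± 261 CPM, and CNN1 by -3.18 ± 0.53. Of 13 blood endothelial markers, 4 fell and none rose (6 adjusted over the list alone), with a median of -0.56 (-0.49 and -0.81, adjusted p = 0.00162), lost with an estimated correlation (adjusted p = 0.234). CDH5, vascular cadherin, changed by -1.66 ± 0.28 and KDR by -1.58 ± 0.29. Of 7 lymphatic endothelial markers, 1 rose and 5 fell, with the same numbers adjusted over the list alone. LYVE1 changed by -2.87 ± 0.61 and RELN by -2.45 ± 0.44, while PDPN, which macrophages, fibroblasts and keratinocytes can also express, rose by 1.83 ± 0.47 (3.61 in set 1 and 0.95 in set 2, adjusted p = 0.215 in the latter). PROX1 (-1.80 ± 0.52) and TFF3 (-3.36 ± 0.99), named after their values were seen, missed the threshold without control replicate 5 (-1.41 and -2.88, adjusted p = 0.116 and 0.0845). The lymphatic median was -1.93 (-0.72 and -2.66, adjusted p = 0.00611), lost with an estimated correlation (adjusted p = 0.234) and in set 1 alone (adjusted p = 0.0777).

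Of 10 nerve and Schwann cell markers, 5 fell and none rose, with the same numbers adjusted over the list alone, with a median of -2.13 (-2.32 and -1.89, adjusted p = 0.00131), lost with an estimated correlation (adjusted p = 0.111). SCN7A changed by -3.78 ± 0.73, SOX10, also of melanocytes and sweat glands, by -2.54 ± 0.69, and CDH19 by -1.93 ± 0.48. Of 8 melanocyte markers, 3 fell and none rose (4 adjusted over the list alone), with a median of -1.48 (-1.14 and -1.69, adjusted p = 0.00567), lost with an estimated correlation (adjusted p = 0.234). DCT, a melanin synthesis enzyme, changed by -2.29 ± 0.41. Of 10 skeletal muscle markers 7 were measurable, 2 fell and none rose, with the same numbers adjusted over the list alone, and the list did not shift (median -0.04, -0.76 and 0.24, mean -0.79, adjusted p = 0.328). MB, myoglobin, changed by -4.30 ± 1.21, from 0.899 ± 0.811 to 0.0432 ± 0.0654 CPM.

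Metabolism was read from adipocyte, insulin signalling and glycolysis genes. Of 14 adipocyte markers, 4 fell and none rose (7 adjusted over the list alone), with a median of -2.09 (-2.11 and -2.07, adjusted p = 6.69e-07), lost with an estimated correlation (adjusted p = 0.163). FABP4, the adipocyte fatty acid carrier, changed by -3.48 ± 0.83, from 197 ± 151 to 17.7 ± 29.1 CPM. Its call ended in set 1 alone and with the level of mitochondrially encoded RNA as a covariate (-2.08 in each, adjusted p = 0.237 and 0.069). Of 12 insulin signalling genes, 4 fell and none rose (6 adjusted over the list alone), with a median of -0.42 (-0.44 and -0.56, adjusted p = 0.0136), lost with an estimated correlation (adjusted p = 0.0963) and with that covariate (median -0.37, adjusted p = 0.0894). PIK3R1, a regulatory subunit of PI3 kinase, changed by -1.06 ± 0.19 and IRS1 by -0.83 ± 0.24. Of 15 hypoxia and glycolysis genes, 5 rose and none fell, with the same numbers adjusted over the list alone. HK2, a hexokinase, rose by 2.43 ± 0.44, PFKFB4 by 2.35 ± 0.40, PGK1 by 1.39 ± 0.26 and ALDOA by 1.23 ± 0.25. VEGFA (1.40 ± 0.34), the vascular growth factor, was named after its value was seen. Their median was 0.45 (0.91 and 0.78), and 0.80 and 0.87 without control replicates 1 and 2. The list was higher (adjusted p = 0.00611), but not with an estimated correlation (adjusted p = 0.296).

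The remaining lists describe tissue state and sample quality. None of 14 cell cycle genes passed, with the same numbers adjusted over the list alone (median 0.24, 0.91 and -0.18, adjusted p = 0.654, and 0.0123 in set 1 alone), and MKI67, a proliferation marker, had a change of 0.47 ± 0.29 (adjusted p = 0.289), and passed without control replicate 4 (0.85). Of 12 immediate early and heat shock genes, which respond to tissue handling, 1 rose and 1 fell, with the same numbers adjusted over the list alone, and the list did not shift (median -0.13, -0.19 and -0.18, adjusted p = 0.357). JUNB rose by 1.36 ± 0.34. Of 6 red blood cell genes, 4 fell and none rose (5 adjusted over the list alone), with a median of -4.14 (-3.62 and -4.47, adjusted p = 7.83e-05), lost with an estimated correlation (adjusted p = 0.0617). HBB, beta globin, changed by -3.98 ± 0.86, from 359 ± 309 to 22.7 ± 29 CPM. Of 16 position-associated HOX genes 14 were measurable, 1 fell and none rose, with the same numbers adjusted over the list alone, with a median of -1.03 (-0.48 and -1.17, adjusted p = 0.0122), which was -0.68 without control replicate 5. That call was lost with an estimated correlation (adjusted p = 0.234) and in set 1 alone (adjusted p = 0.0685). Of the 13 mitochondrially encoded protein-coding genes, 11 fell and none rose (12 adjusted over the list alone), with a median of -2.34 (-0.13 and -2.48). MT-ND3 changed by -2.11 ± 0.53, from 20.5 ± 15.1 to 4.73 ± 4.64 CPM. This list was lower (adjusted p = 0.000295), but not with an estimated correlation (adjusted p = 0.324) nor in set 1 alone (adjusted p = 0.183). The ribosomal RNA genes of the mitochondrion, MT-RNR1 (-0.83 ± 0.67, adjusted p = 0.441) and MT-RNR2 (-0.14 ± 0.45, adjusted p = 0.878), named after their values were seen, did not pass. All mitochondrial genes together took 0.692% ± 0.409 of counts in control and 0.519% ± 0.300 in NL, with means of 0.25% and 0.61% in set 1 and 0.99% and 0.46% in set 2.

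Of the 49 lists, 38 shifted, 20 up and 18 down. With an estimated correlation 10 shifted, 8 up and 2 down. RNA of the 13 mitochondrial protein-coding genes moved with the groups and with the library sets, and with its mean level as a covariate, an alternative chosen after seeing the data, the mast cell, elastic fibre, fibroblast, insulin signalling and HOX lists no longer passed (medians -0.05, -0.53, -0.51, -0.37 and -0.48, adjusted p = 0.116, 0.0582, 0.263, 0.0894 and 0.192). Of 157 named genes past the threshold 15 lost their call with this covariate. Besides AHR and FABP4, the change moved by over 1.5 times for IL6ST (-0.51), LOX (-0.51), PTPN11 (-0.23), FBLN5 (-0.54) and KRTAP3-3 (-5.52), and JAK2 (0.65, adjusted p = 0.106) and DCN (-0.90, adjusted p = 0.0575) also lost their call. Besides AHR, FABP4, TP63 and PDPN, genes that moved by over 1.5 times and lost their call in 1 library set alone were, in set 1, MUC7 (-4.43), STRA6 (3.96), IBSP (4.25), IL6ST (-0.49), PTPN11 (-0.20), SPARC (-0.84), COL14A1 (-0.86), LOX (-0.23), FBLN5 (-0.68), DCN (-0.62), CDH5 (-1.10), KDR (-0.76), PROX1 (-0.72) and MT-ND3 (-0.94), and, in set 2, COL12A1 (0.27), LTBP4 (-0.59), CXCL13 (1.89) and ELOVL3 (-2.32).

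Across the 17 NL samples, the interferon gamma response score was compared with 4 other scores, to ask which cell type genes vary with it between lesions, and no member is shared with any of them. Its correlation with the JAK and STAT score was r = 0.78 (permutation p = 8e-05, adjusted 0.00032) and rho = 0.86 (permutation p = 3e-05, adjusted 0.00012). Without the 2 samples farthest from the median interferon score r was 0.74. Within the library sets r was 0.92 in set 1 (n = 7, exact permutation p = 0.00437) and 0.67 in set 2 (n = 10, permutation p = 0.0327), where it did not pass adjusted over the 4 relations (0.132). With T cell markers r was 0.68 (permutation p = 0.00344, adjusted 0.00688) and rho 0.45 (permutation p = 0.0689, adjusted 0.127). That relation rested on the 2 farthest samples, without which r was 0.18, and it was 0.88 in set 1 (exact permutation p = 0.0103, n = 7) but 0.21 in set 2 (permutation p = 0.556). With macrophage markers r was 0.47 (permutation p = 0.0562, adjusted 0.075) and rho 0.42 (permutation p = 0.0949, adjusted 0.127), with 0.29 without the 2 farthest samples and 0.85 and 0.25 within the sets. With fibroblast markers r was -0.09 (permutation p = 0.742, adjusted 0.742) and rho -0.12 (permutation p = 0.646), with -0.12 without the 2 farthest samples and -0.26 and 0.08 within the sets. All of these tests were two-sided.

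**Figure D4:**
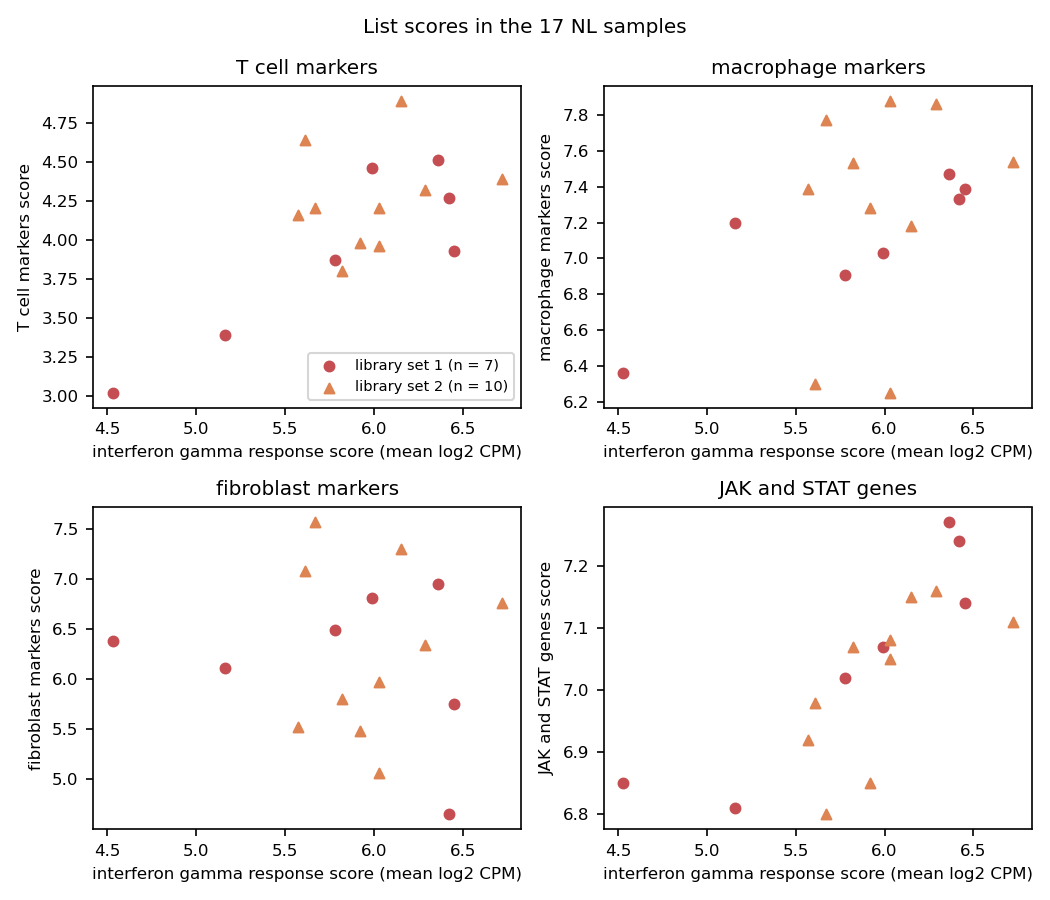
Each point is 1 of the 17 NL samples, with the interferon gamma response score (mean log2 CPM) on the horizontal axis and the score of another list on the vertical axis, circles for library set 1 (n = 7) and triangles for library set 2 (n = 10). The JAK and STAT score rises with the interferon score in both sets (r = 0.92 and 0.67), and the fibroblast score does not follow it (r = -0.26 and 0.08).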

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

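The tests of sweat gland genes against basal keratinocyte genes and of mitochondrial protein-coding RNA against the library sets and against mitochondrial ribosomal RNA were chosen after the result was seen.

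Among the 5 control samples, 1 sample stood apart from the other 4 in 9 of 215 results tested, by a gap that took more than 0.71 of the whole range. Chance gives about 1 in 20. The lowest basal keratinocyte score was 8.35 against 8.69 to 8.81 (0.737 of the range), and the lowest skeletal muscle score 0.52 against 2.67 to 3.08 (0.839). Log2 CPM was lowest in 1 control for COL11A1 (2.13 against 5.86 to 6.95, 0.773), ADAMDEC1 (-4.74 against 0.67 to 2.63, 0.734) and TFF3 (-3.30 against 1.18 to 2.41, 0.785). It was highest in 1 control for STAT3 (8.99 against 7.99 to 8.21, 0.786) and CXCR3 (-1.74 against -5.41 to -4.85, 0.847). IL23A (-4.31 against -5.41) and IL27 (-4.95 against -5.41) were detected in 1 control alone, which gives 1.0 by construction.

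Sweat gland genes were lower in NL, with a median of -3.79. Even dilution of the whole biopsy by immune cells would lower resident lists alike, but this median lay below the lower quartile of basal keratinocyte genes (-0.88). That list is epidermal, so the comparison cannot decide on dilution confined to the dermis, which was not tested. Other resident lists fell by unlike amounts, with medians of -3.60 for hair follicle, -2.13 for nerve, -1.77 for smooth muscle, -1.03 for fibroblast and -0.56 for blood endothelial genes. A single gland-rich control biopsy was argued against by the median nearest 0 without 1 control, -3.13, and the library sets by the median nearest 0 within a set, -2.62. A loss of glands in lesions and a difference in depth or body site of the biopsies stay open: lists that bear on site and depth were lower too, HOX genes with a median of -1.03 (adjusted p = 0.0122, and 0.234 with an estimated correlation) and adipocyte markers with -2.09 (adjusted p = 6.69e-07, and 0.163).

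Interferon gamma response genes were higher in NL, with a median of 1.79. The lowest median within a library set was 1.51, which argues against the sets as the cause. With the mean T cell and macrophage marker score as a covariate the median was 0.49 and 1 of 22 members passed, while over all genes 537 were higher and 605 lower. That score had r = 0.88 with the group, so more leukocytes per biopsy and more interferon response per cell cannot be told apart here.

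RNA of the 13 mitochondrial protein-coding genes was lower in NL, with a median of -2.34 (adjusted p = 0.000295, and 0.324 with an estimated correlation). That of the 2 mitochondrial ribosomal RNA genes did not pass. With the library set as a term the median was -1.80 and 11 of 13 members passed, which argues against a difference between the sets as the whole cause. Whether the fall is confined to set 2 stays open: the median was -0.13 in set 1, which has 2 controls, and -2.48 in set 2, and the change of none of the 13 members differed between the sets (lowest adjusted p = 0.104 over the list). Fewer mitochondria per biopsy would lower both kinds of RNA alike, if both are captured in proportion to their amount, which was not tested. The change of the coding genes less that of the ribosomal RNA genes was -1.54 ± 0.41 (SE, exact permutation p = 0.00589, and -1.57 and -1.49 in sets 1 and 2). On that condition it argues against fewer mitochondria as the whole cause. In set 1, however, the coding median was -0.13, and mitochondrial genes together took 0.25% of counts in control and 0.61% in NL. The difference in set 1 therefore cannot be read as a fall of coding RNA alone. A part of fewer mitochondria in the fall stays open, since the median of 83 nuclear genes of the respiratory chain was -0.31, between the bounds set for the test. Degradation of the coding RNA was not tested.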

How the results depend on the processing

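Alternatives by library set, without receptor genes and with the mitochondrial covariate were chosen after seeing the data. The count of 4045 changed genes lay between 3099 and 5380 under the other settings that kept all libraries or set 1, and was 2419 in set 2 alone. With the T cell and macrophage score as a covariate, which follows the group, 537 genes were higher and 605 lower. The 2914 changes above 2-fold became 1800 in set 2 alone, 1762 with limma on log2(RPKM + 1) and 847 with glmTreat. The glmTreat test asks for a larger change. Without the fold cut, limma on log2(RPKM + 1) passed 4062 genes, and with 0.1 in place of 1 it passed 3085 above 2-fold. The lower count with limma thus went with the constant added before the log. For set 2 the cause was not tested. Of the called genes 55.3% were higher, but 43.9% without a low count filter, 46.8% with limma-voom, 49.3% with at least 1 CPM in 5 samples, and 49.7% and 49% without NL replicates 10 and 17, so which direction held more genes depended on these choices. The median log2 change of all genes was 0.054 with TMM and between 0.031 and 0.076 with the other scalings. Without 1 library in turn the counts ran from 2915 to 4424, from 2274 to 3063 above 2-fold, and from 38 to 39 lists. Of 157 named genes past the threshold, 135 never lost their call under the alternatives chosen beforehand that kept all libraries, and 136 never without each library in turn. Fits whose filter left a gene out were skipped for that gene: with at least 1 CPM in 5 samples, 143 of the 157 were tested. The glmTreat test is not part of this count. In set 1 alone 47 of 156 lost their call, in set 2 alone 42 of 155, and with the mitochondrial covariate 15 of 157. KRTAP3-3 ran from -9.03 to 0.19, the latter without control replicate 5, when 1 library was left out.

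With an estimated correlation 10 lists shifted in place of 38. This alters the p alone, so the medians of the lists that lost their call are by construction those of the preset test: receptors 0.98, cytokines 1.42, type I interferon 0.89, macrophage markers 1.72, lysosome 0.60, cytotoxic 1.60, B cell 1.48, plasma cell 5.45, mast cell -0.71, lymphoid chemokines 1.83, elastic fibre -1.04, fibroblast -1.03, matrix-degrading enzymes 0.89, TGF-beta 0.75, basal -0.63 and cornified keratinocyte -1.08, hair -3.60, adipocyte -2.09, blood endothelial -0.56, lymphatic -1.93, smooth muscle -1.77, nerve -2.13, melanocyte -1.48, hypoxia 0.45, insulin -0.42, red blood cell -4.14, HOX -1.03 and mitochondrially encoded -2.34. With fry the feedback list (-0.10), lipid handling (0.72) and neutrophil markers (0.97) passed, and on ranks lymphoid chemokines (1.83) did not. Lipid handling also passed with total counts (0.74), without a filter (0.72), without receptor genes (0.71) and with the mitochondrial covariate (0.86). Without 1 library in turn its median ran from 0.61 to 0.78, and it passed without 10 of them, while stressed keratinocyte genes ran from 1.67 to 3.81 and passed without control replicate 4. Hair genes did not pass with at least 1 CPM in 5 samples (-1.05).

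In set 1 alone, which has 2 controls, the mast cell (-0.14), elastic fibre (-0.58), fibroblast (-0.12), basal keratinocyte (-0.33), lymphatic (-0.72), HOX (-0.48) and mitochondrially encoded (-0.13) lists lost their call, and fibrillar collagen (0.81), stressed keratinocyte (3.56) and cell cycle genes (0.91) passed. In set 2 alone cytokines (0.24), lysosome (0.17), lymphoid chemokines (1.49), matrix-degrading enzymes (0.38) and TGF-beta (0.63) lost theirs. With the mitochondrial covariate mast cell (-0.05), elastic fibre (-0.53), fibroblast (-0.51), insulin (-0.37) and HOX (-0.48) lists lost theirs, and fibrillar collagen (0.40) passed. For these list calls the cause was not tested. The value of -0.02 for mitochondrially encoded genes with that covariate follows by construction, since the covariate is their own mean. MT-RNR1 (-0.83) was 1.28 with it.

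The interferon gamma score had r = 0.18 with T cell markers without the 2 farthest samples and 0.21 in set 2, and r = 0.67 with JAK and STAT genes in set 2, which did not pass after adjustment. With macrophage markers r passed on log2(RPKM + 1) (0.52) and in set 1 (0.85). For these the cause was not tested. With 5 controls, simulated 2-fold changes were recovered for 22% of genes and 4-fold changes for 74%, so smaller changes can be missed. The simulated changes were in genes with a mean log2 CPM of at least 1, and were fewer than the genes called in the real data. These shares are therefore not recovery rates for all genes of the real comparison.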

Other observations

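The genes, gene groups and tests of the first 3 paragraphs were chosen after their values were seen.

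Immunoglobulin segments gained counts in NL. Of 153 tested segments 129 rose, and together they went from 388 ± 424 CPM in control to 52040 ± 57630 CPM in NL (SD, n = 5 and 17). IGHG1, an IgG heavy chain gene, rose by 7.49 ± 1.66 log2 units and IGHA1, an IgA heavy chain gene, by 6.41 ± 1.51, each above the control mean in 17 of 17 NL samples. The segments are near-identical copies of one another, so single values are uncertain. IgG genes took 58.5% ± 26.6 of heavy chain constant region counts in control and 79.6% ± 16.8 in NL (exact permutation p = 0.0333, adjusted 0.0998 over 3 comparisons, higher in 15 of 17 NL samples), with 55.6 and 72% in set 1 and 60.5 and 84.9% in set 2. The IgM share was 23.5% ± 12.6 and 11.6% ± 15.6 (exact permutation p = 0.113, adjusted 0.169), with 13.4 and 15.8% in set 1 and 30.3 and 8.7% in set 2, and the IgA share 16.6% ± 23.5 and 8.6% ± 11.7 (exact permutation p = 0.231, adjusted 0.231), with 29.6 and 12% in set 1 and 8 and 6.3% in set 2. None of the 3 shares passed after adjustment. Of 134 T cell receptor segments 61 rose, together from 49.8 ± 31.5 to 269 ± 79.5 CPM.

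Among single genes outside the lists, 7 that rose are given here, with no test of a theme behind them. FBP1, a gluconeogenic enzyme also made by macrophages, rose by 5.91 ± 0.80, HK3, a hexokinase of myeloid cells, by 4.68 ± 0.53, and LILRB4, an inhibitory receptor, by 4.78 ± 0.64. ALOX5, the enzyme that starts leukotriene synthesis, rose by 3.53 ± 0.46, the integrin genes ITGAX and ITGB2 by 3.89 ± 0.47 and 3.39 ± 0.35, and CORO1A, a leukocyte actin regulator, by 2.81 ± 0.27.

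Another 3 single genes outside the lists that fell are given likewise. PDK4, which restrains glucose oxidation, changed by -4.17 ± 0.48, and PPARGC1A, a coactivator of mitochondrial biogenesis, by -3.41 ± 0.54. SLC12A2, a chloride cotransporter of secretory epithelia such as sweat glands, changed by -3.74 ± 0.31, from 449 ± 285 to 33.6 ± 16.3 CPM. All 3 lay below the control mean in every one of the 17 NL samples.

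Other splits of the libraries into 17 and 5 were compared with the real split, 100 in all with the real one among them. For the 4045 changed genes 1 of the 100 splits, the real one, gave as many, and the highest other gave 136. For changes above 2-fold 1 split gave as many as 2914, with 104 the highest other. For the gene lists 1 split gave as many as 38, with 32 the highest other and a median of 13. Chance can be excluded at the threshold of 0.05 for these 3 counts, though the other splits shifted up to 32 lists.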
